A study of Mus musculus with 8 samples.

How the data were processed

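The series compared subcutaneous fat of 4 placebo and 4 NBC-supplemented diabetic male mice, 1 Affymetrix Mouse Genome 430 2.0 array per mouse with biotin-labelled total RNA, per the labels and the series design. The deposited values are one signal intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes, which carry no version. MAS5 in general sets perfect-match probes against their mismatch partners, which leaves dim transcripts noisy. In the deposited intensities the mean trimmed by 2% at each end was 1500.01 on all 8 arrays, so the values were used as deposited, with no further scaling. Such scaling lets a set of very abundant transcripts in one array lower the other signals of that array slightly. The scanner, the scaling software, the slide or scan batch and the diabetic strain are not given in the sources used here, so no batch could be entered in a fit.

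Groups and mouse numbers were taken from the sample titles. The labels describe separate mice, and no mouse number occurs in both groups. Spearman correlations between arrays over the probe sets kept were 0.941 to 0.975 within and 0.945 to 0.968 between groups, and at most 0.0776% of signals were identical in any pair, so no array was a copy of another.

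The table held 45101 probe sets, of which 64 control probe sets were left out of the tests. Probe sets were named through the platform annotation given for the series, with symbols checked through Entrez identifiers against RefSeq (0 symbols changed). It named 1 gene for 34945 probe sets, several for 932 and none for 9160, and the last 2 kinds were tested but not named. No genome build is named for the platform in the sources used here, so no coordinates are given. Signals were transformed as log2(signal + 26), where 26 is the 10th percentile of all values, so that log2 differences understate the change of dim transcripts. Probe sets whose mean log2 value over the 8 arrays was at or above the median of all probe sets were kept (22519 probe sets, with a limit at a signal of 275). A gene was represented by its kept probe set with the highest mean, which gave 11662 genes. Of the 69 genes examined, 23 had other kept probe sets. In 15 of these at least 1 went the other way or was more than 1.5 times larger or smaller in log2 difference, among them Ckm, Nampt and Idh3a.

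NBC was compared with placebo per probe set with limma 3.58.1 (lmFit and eBayes, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment over the 22519 probe sets and a threshold of 0.05. Standard errors of log2 differences are the moderated ones of this fit, and SDs are those of the linear signals. Gene lists were tested on representatives with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 27 lists, with an estimated correlation and fry as alternatives. Each list also had a score per mouse, tested with a two-sided exact permutation test over all splits of 4 against 4, whose smallest p is 0.0286. Members were also adjusted over the list alone.

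The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The lists held 600 distinct genes, of which 470 were measured, 82 lay below the filter and 48 were not named in the annotation used. They covered skeletal muscle contraction, skeletal muscle calcium handling and energy supply, muscle development regulators, glycolysis, brown and beige adipocyte thermogenesis, lipogenesis, lipolysis and lipid droplets, niacin receptor and NAD metabolism, insulin signalling, adipocyte identity, macrophages, the respiratory chain and citrate cycle and fatty acid oxidation. Others covered antioxidants, metal binding and transport, extracellular matrix, lymphocytes, endothelium, skin and epithelium, nerve, smooth muscle, erythroid cells, immediate early and heat shock genes, endoplasmic reticulum stress, the circadian clock, cholesterol synthesis and the cell cycle. One more list, of 5 genes recalled from the study, was not tested as a set, and the muscle and thermogenesis lists were drawn up with knowledge of the study. The rule named the 12 genes per direction with the largest change past the threshold and no overlap between groups, filled up, where fewer passed, with the genes of smallest unadjusted p and no overlap. To these it added up to 4 members of each list with the smallest p, the recalled genes, Lepr, Lep, Hcar2, Xist and the Gapdh and beta-actin control probe sets, and the text gives those that carry each comparison.

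The fit was tested on simulated arrays of the same 22519 probe sets with the real spreads. Of 100 probe sets changed 2-fold, 56% were recovered, and of 100 changed 4-fold, 82%, with 7 false calls, and 0 calls were made when none was changed. At the median spread the shares were 98% and 100%. With 1 list shifted, 1 list passed, and with none shifted, 0. Genes were simulated as independent, while in the real arrays the estimated correlation within a list reached 0.694 (lymphocytes). This check therefore cannot show how camera behaves on the real lists. Differences shared by many genes of a mouse were not simulated either, so the recovered shares need not hold on the real arrays.

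Alternatives were quantile normalization, median centring, no pseudocount, a pseudocount of 97 (the 25th percentile), no filter, a stricter filter at the 75th percentile, trend and robust settings, array weights, each array left out in turn, the mean of all kept probe sets of a gene, both other list tests and the muscle contraction score as a covariate. The Gapdh 3' to 5' ratio as a covariate, and leaving out NBC mice 5 and 11, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.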

Results

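Subcutaneous fat was taken from 8 male diabetic mice that had been 8 weeks old per the labels and had been gavaged for 10 weeks on 5 days per week. The 4 placebo mice (numbered 6, 8, 10 and 14) received water, and the 4 supplemented mice (numbered 5, 9, 11 and 13) received niacin-bound chromium (NBC), a complex of trivalent chromium with nicotinic acid, at 10 mg per kg body weight. Each mouse gave 1 Affymetrix Mouse Genome 430 2.0 array, on which a transcript is read by 1 or more probe sets. The mean signal trimmed by 2% at each end was 1500.01 on every array, and the median signal was 306 ± 15.6 (SD, n = 4) in placebo and 309 ± 23.4 (SD, n = 4) in NBC mice. After dim probe sets were set aside, 22519 probe sets that stood for 11662 named genes were tested. The number of arrays limits the precision of every value given here.

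The comparison of the supplemented with the placebo mice asked which transcripts of this fat depot differed after oral NBC. The widest differences were in transcripts of fast skeletal muscle fibres. The mean signal in NBC mice was 16.7 (Mylpf) to 23.6 (Actn3) times that in placebo mice for the 4 contraction genes named. These transcripts stood high in 3 of the 4 NBC mice and at the placebo level in the remaining one, mouse 9. Transcripts of the lipid droplet protein Cidea and of the mitochondrial uncoupling protein Ucp1 had lower means in NBC mice. Means of the fatty acid oxidation and mitochondrial lists lay slightly lower in NBC mice, and those of the metal transport, extracellular matrix and macrophage lists slightly higher. Scores of the extracellular matrix and macrophage lists overlapped between the groups. With an estimated correlation between genes no list passed the threshold.

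No single probe set passed the threshold in limma's moderated test with Benjamini-Hochberg adjustment (0 of 22519, smallest adjusted p = 0.653). At an unadjusted p under 0.05 there were 1400 probe sets, 739 higher and 661 lower in NBC, where 1126 would arise by chance. With 1 mouse left out this count ranged from 1037 (without placebo mouse 8) to 2549 (without NBC mouse 9, where 35.7% were higher in NBC). The 4 values of each group did not overlap for 458 genes (198 higher and 260 lower in NBC), which is 3.93% of the genes against 2.86% by chance. The genes below are those the fixed rule selected, and none of them passed over all probe sets tested. With camera at a preset correlation 7 of 27 gene lists passed, and 12 of the 35 splits of the 8 arrays into 4 and 4 gave at least as many. With an estimated correlation 0 of the 27 lists passed, as did 0 in fry's test for change in one direction.

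Of the 19 measured members of the skeletal muscle contraction list, 17 had a log2 difference (NBC minus placebo) above 0, with a list mean of 2.12. The alpha-actinin of fast fibres, Actn3 (probe set 1418677_at), averaged 322 ± 215 (SD, n = 4) in placebo and 7574 ± 4697 (SD, n = 4) in NBC mice, a log2 difference of 4.03 with a standard error of 0.91. The fast troponin subunits Tnni2 (1416889_at) and Tnnc2 (1417464_at) differed by 4.06 (SE 0.95) and 3.81 (SE 0.91), and the fast regulatory light chain Mylpf (1448371_at) by 3.72 (SE 0.89). In the list of muscle calcium handling and energy supply, 15 of 17 measured members lay above 0 and the mean was 1.58. It held the muscle creatine kinase Ckm (1417614_at; 4.02, SE 0.93), the calcium buffer parvalbumin, Pvalb (1417653_at; 4.18, SE 0.93), the muscle enolase Eno3 (1417951_at; 2.6, SE 0.56) and the calsequestrin of the sarcoplasmic reticulum, Casq1 (1422598_at; 1.91, SE 0.45). Ckm read 279, 648, 1373 and 310 in placebo mice 6, 8, 10 and 14, and 15116, 21901, 1081 and 18305 in NBC mice 13, 11, 9 and 5. Eno3, Pvalb and Casq1 had no overlap between the groups, while Ckm, Actn3, Tnni2, Tnnc2 and Mylpf overlapped because NBC mouse 9 lay below placebo mouse 10. Myl3 and Tnnc1, isoforms of slow and cardiac fibres that were picked after their values were seen, differed by -0.057 (SE 0.36) and 0.20 (SE 0.15).

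**Figure D1:**
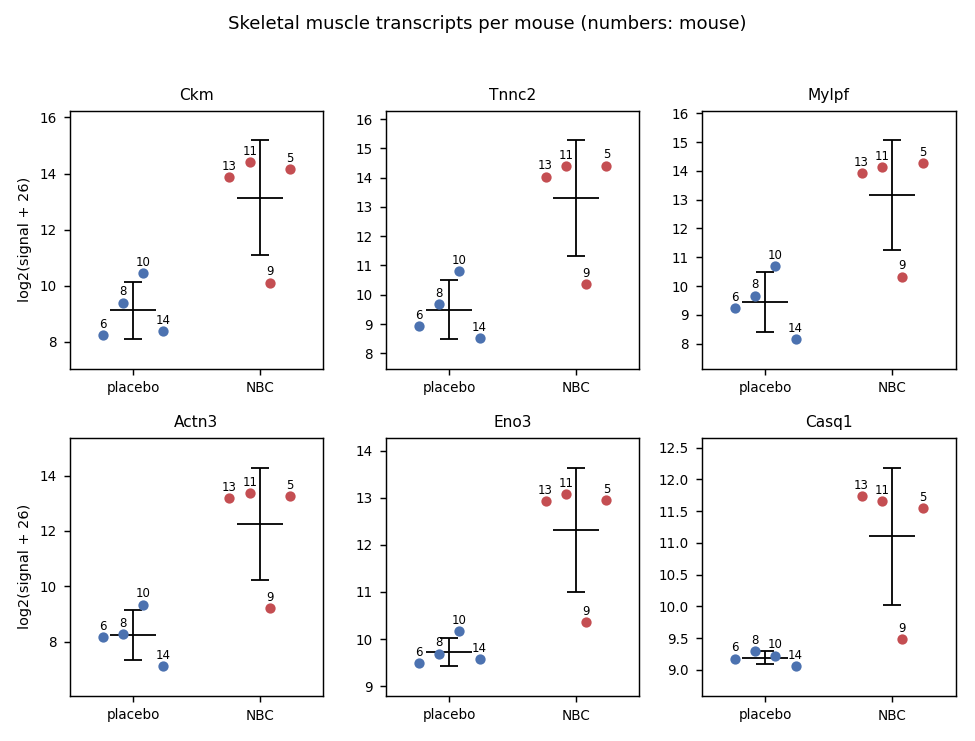
Expression of 6 skeletal muscle transcripts in each mouse, as log2 of the signal plus 26 on the vertical axis, for placebo (blue) and NBC (red) mice; points are single mice with their numbers, and black lines are the group mean and 1 SD (n = 4). Ckm lies at 15116 to 21901 signal units in NBC mice 13, 11 and 5, and at 1081 in NBC mouse 9.

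With a preset correlation between genes, limma's camera placed both muscle lists past the threshold (adjusted p = 4.3e-15 and 3.3e-12). The adjusted p was 0.218 for each list with an estimated correlation. Adjusted over the list alone, 12 of 19 and 8 of 17 members passed, all of them higher in NBC. The contraction score per mouse was -1.06 ± 0.65 (SD, n = 4) in placebo and 1.06 ± 1.22 (SD, n = 4) in NBC mice. Its two-sided exact permutation p was 0.0571 (0.309 after adjustment over 27 lists), where the smallest p that 4 against 4 allows is 0.0286. These lists were drawn up with knowledge of the study and are not independent evidence of their direction. Without NBC mouse 9, 18 probe sets of 17 genes passed limma's adjusted threshold, 17 higher and 1 lower in NBC, and 16 of the 18 belonged to the muscle lists. The 2 others were read from Apobec2, a muscle-expressed member of the cytidine deaminase family, and from Klhl8 (1433526_at, lower in NBC), both named because they alone fell outside the lists. The brighter probe set of Klhl8, 1454637_at, differed by only -0.10 (SE 0.15) over all 8 mice, with overlap. The Gapdh 3' to 5' signal ratio, a sign of RNA integrity, stood highest in NBC mice 5 (1.47) and 11 (1.28), against 0.92 to 1.04 in placebo mice, 1.12 in NBC mouse 13 and 0.84 in NBC mouse 9.

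Probe sets of the tropomyosin gene Tpm1, one of the genes recalled from the study, disagreed. The brightest one, 1423721_at, read 4890 ± 272 (SD, n = 4) in placebo and 4428 ± 361 (SD, n = 4) in NBC mice, a log2 difference of -0.14 (SE 0.11). Another, 1423049_a_at, read 2150 ± 727 and 7445 ± 3123 (SD, n = 4 each), a log2 difference of 1.70 (SE 0.40). It was high in NBC mice 13 (9981), 11 (8472) and 5 (8442) and not in NBC mouse 9 (2887). The desmin gene Des, an intermediate filament gene of all muscle types and a member of the smooth muscle list, followed this pattern too, with 1238, 2388 and 2489 in NBC mice 13, 11 and 5, 546 in NBC mouse 9 and 438 to 758 in placebo mice.

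Cidea (1417956_at), which coats lipid droplets and is abundant in brown adipocytes, averaged 1671 ± 374 (SD, n = 4) in placebo and 813 ± 92.8 (SD, n = 4) in NBC mice, with no overlap and a log2 difference of -0.996 (SE 0.18). It ranked 6 among the 11662 genes by p and missed the threshold over all probe sets. It passed adjusted over the list alone (adjusted p = 0.0066 in the thermogenesis list and 0.0077 in the lipolysis list). Ucp1 (1418197_at), which dissipates the mitochondrial proton gradient as heat, averaged 3260 ± 1242 (SD, n = 4) and 1228 ± 595 (SD, n = 4), a log2 difference of -1.39 (SE 0.40), with placebo mouse 10 at 1408 and NBC mouse 13 at 2078. Both genes are among those recalled from the study, which singled them out on these samples. Of the 18 measured members of the brown and beige adipocyte thermogenesis list, 13 lay below 0 and 5 above, the mean log2 difference was -0.19 and the list missed the threshold (camera adjusted p = 0.0697, and 0.534 with an estimated correlation). It passed in 7 of 21 alternatives, and without placebo mouse 10 its mean was -0.292 (camera adjusted p = 0.0017). The list holds Cidea and Ucp1, so its calls are not support independent of these genes. Its other 16 members had a median of -0.0898 over all mice. The acyl-CoA thioesterase Acot11 lay higher in NBC with no overlap (0.44, SE 0.15), and the pyruvate dehydrogenase kinase Pdk4 lower (-0.62, SE 0.26).

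**Figure D2:**
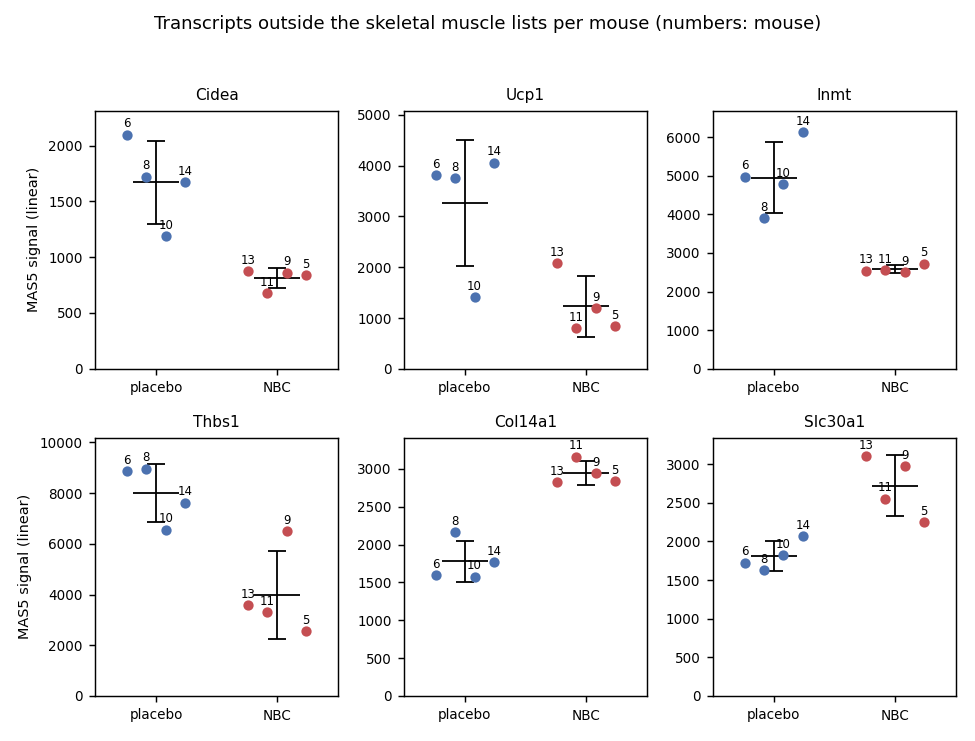
MAS5 signal on a linear axis from 0 of 6 transcripts outside the muscle lists in each placebo (blue) and NBC (red) mouse; points are single mice with their numbers, and black lines are the group mean and 1 SD (n = 4). Cidea lies between 1188 and 2099 in placebo mice and between 675 and 875 in NBC mice.

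The fatty acid oxidation list had 19 of 21 measured members below 0 and a mean log2 difference of -0.156 (camera adjusted p = 0.00047, preset correlation). The adjusted p was 0.129 with an estimated correlation. Its examples included the dienoyl-CoA isomerase Ech1 (-0.23, SE 0.10) and the medium-chain acyl-CoA dehydrogenase Acadm (-0.22, SE 0.10), each with no overlap between groups, and Pdk4, which restrains glucose oxidation. The list of the respiratory chain and citrate cycle had 25 of 30 members below 0 and a mean of -0.0898 (camera adjusted p = 0.0039), with an adjusted p of 0.218 with an estimated correlation. The citrate cycle enzyme Idh3a read 27183 ± 833 in placebo and 21291 ± 3591 in NBC mice (SD, n = 4 each; log2 difference -0.37, SE 0.14), and the succinate dehydrogenase subunit Sdhc differed by -0.21 (SE 0.11), though its second kept probe set gave 0.093 (SE 0.22). No member of either list passed adjusted over the list alone. For both lists the score separated the 4 placebo from the 4 NBC mice completely (exact two-sided permutation p = 0.0286, the smallest possible, and 0.257 after adjustment over 27 lists). For the mitochondrial list this separation was very narrow, with placebo mouse 14 at 0.0056 and NBC mouse 5 at 0.0035. The same mice stood at 0.047 and -0.026 for fatty acid oxidation. Without NBC mouse 9 the mitochondrial list missed the threshold (mean -0.0736, camera adjusted p = 0.0625). The adipocyte identity list, which missed the threshold, had a similar mean over all mice (-0.0864). A shift particular to the mitochondrial list is therefore not shown.

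The metal binding and transport list had 14 of 17 measured members above 0, with a mean log2 difference of 0.167 (camera adjusted p = 0.0104) and complete separation of the groups by score (exact permutation p = 0.0286, adjusted 0.257). The adjusted p was 0.218 with an estimated correlation. The zinc exporter Slc30a1 (1436164_at) averaged 1811 ± 190 in placebo and 2724 ± 395 in NBC mice (SD, n = 4 each; log2 difference 0.58, SE 0.14), and was the only member past the threshold adjusted over the list alone (adjusted p = 0.0479). Its other kept probe set, 1422786_at, went the other way (-0.16, SE 0.20), and the mean of both probe sets differed by 0.21. The zinc importer Slc39a1 differed by 0.50 (SE 0.14), also with no overlap. The call of the list was lost without NBC mouse 11 (mean 0.142, camera adjusted p = 0.0521) and without NBC mouse 9 (0.168, camera adjusted p = 0.0537).

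The extracellular matrix and fibroblast list had 22 of 25 measured members above 0 and a mean log2 difference of 0.153 (camera adjusted p = 0.00011). The adjusted p was 0.395 with an estimated correlation, and no member passed adjusted over the list alone. The exact permutation p of the score was 0.143, and NBC mouse 5 (-0.126) lay below all 4 placebo mice. The membrane collagenase Mmp14 (0.56, SE 0.17) and the collagen genes Col6a3 (0.43, SE 0.15) and Col1a1 (0.36, SE 0.14) lay higher in NBC without overlap. Another kept Mmp14 probe set, 1416572_at, gave 0.087 (SE 0.26) and a second one of Col1a1, 1455494_at, gave 0.42 (SE 0.26), both with overlap. Thrombospondin 1, Thbs1, averaged 8009 ± 1143 in placebo and 3986 ± 1730 in NBC mice (SD, n = 4 each; log2 difference -1.08, SE 0.26). It read 3587, 3310 and 2550.5 in NBC mice 13, 11 and 5. NBC mouse 9 (6495.5) lay close to placebo mouse 10 (6561). The second kept Thbs1 probe set, 1450377_at, gave -0.91 (SE 0.36) with overlap. Over the alternatives the Thbs1 difference ranged from -1.34 to -0.310. All 23 measured members of the macrophage and inflammation list lay above 0, with a mean of 0.274 (camera adjusted p = 0.00062), but the adjusted p was 0.534 with an estimated correlation and the exact permutation p of the score 0.371. The acute-phase gene Saa3 read 1456 ± 320 in placebo and 3597 ± 1559 in NBC mice (SD, n = 4 each), and the receptor gene Csf1r of macrophages differed by 0.33 (SE 0.13), or by 0.029 (SE 0.20) in its probe set 1423593_a_at. The macrophage score was highest in NBC mouse 13 (0.68) and lowest in placebo mouse 10 (-0.60). NBC mice 5 (-0.261) and 11 (-0.161) lay below placebo mice 6, 8 and 14 (-0.0467, 0.0160 and 0.0845). The call of the macrophage list was lost without NBC mouse 13 (mean 0.0944, adjusted p = 0.251), without placebo mouse 10 (0.119, adjusted p = 0.153) or without NBC mouse 9 (0.222, adjusted p = 0.0521).

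**Figure D3:**
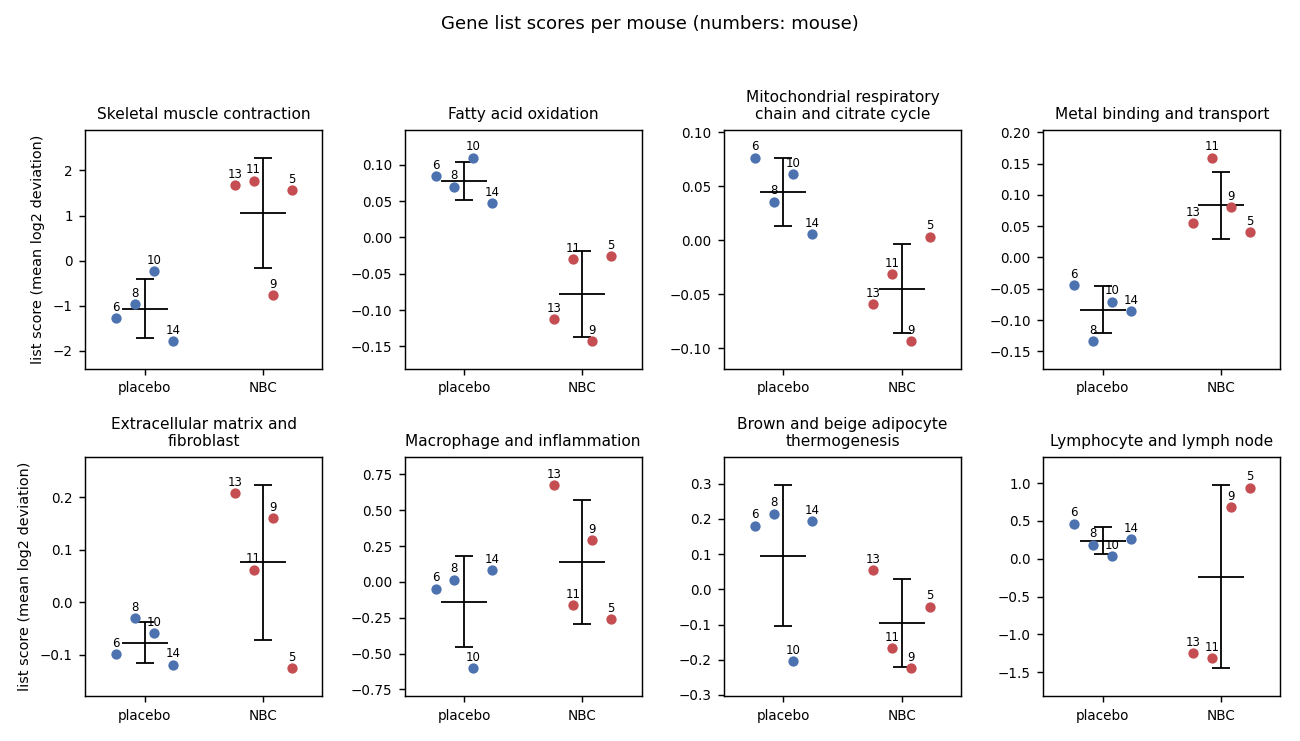
Score of 8 gene lists in each mouse, the mean over members of the log2 value minus its mean over all 8 mice, for placebo (blue) and NBC (red) mice; points are single mice with their numbers, black lines are the group mean and 1 SD (n = 4), and the vertical axes differ between lists. The groups separate without overlap for fatty acid oxidation, metal transport and, very narrowly, the mitochondrial list (0.0056 in placebo mouse 14, 0.0035 in NBC mouse 5). NBC mouse 9 lies at -0.77 among the placebo mice for muscle contraction.

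Outside the lists, the genes with the smallest p among those without overlap went in both directions. The methyltransferase Inmt (1418697_at), ranked 1 of the 11662 genes, averaged 4950 ± 918 in placebo and 2585 ± 93.6 in NBC mice (SD, n = 4 each), a log2 difference of -0.91 (SE 0.15). Among the lower genes, the adhesion receptor Adgrg2 (-0.73), Lmbr1l (-0.98), the potassium channel subunit Kcnmb4 (-0.78), Fbxo21 (-0.66) and Mtcl1 (-0.81) followed. The calcium sensor Ncs1 (-0.86), Proser2 (-0.81), Nxph3 (-0.59), the BMP antagonist chordin, Chrd (-0.77), and the biotin ligase Hlcs (-0.93) completed the 11 lower genes beside Cidea. Among the higher ones, the collagen gene Col14a1 (1427168_a_at) averaged 1777 ± 273 and 2943 ± 158 (SD, n = 4 each; log2 difference 0.73, SE 0.13). Pi16, a marker of adventitial fibroblasts (1.60, SE 0.33), the stromelysin Mmp3 (0.73, SE 0.16) and the platelet-derived growth factor receptor Pdgfrb (0.57, SE 0.13) are likewise expressed by stromal cells. The same rule named 1810064F22Rik (1.53), Gprc5c (1.22), Sgtb (0.98), the imprinted non-coding RNA gene Meg3 (0.53) and the sarcomere gene Myom2 (2.6). None of these passed the adjusted threshold. Several were dim, with a mean signal below the filter limit of 275 in 1 group. In placebo mice these means were 182 for 1810064F22Rik, 190 for Gprc5c and 145 for Myom2. In NBC mice they were 208 for Kcnmb4, 204 for Mtcl1, 208 for Proser2 and 247 for Lmbr1l. Other kept probe sets of Adgrg2 (-0.35, SE 0.26), Col14a1 (0.57, SE 0.19), Fbxo21 (-0.65, SE 0.21) and 2 of Meg3 overlapped.

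The lists for niacin, insulin and lipid storage gave small differences that missed the threshold as fixed. Calls were gained in 8 of 21 alternatives for lipolysis, 5 for adipocyte identity and 1 for lipogenesis, and in 0 for the niacin and insulin lists. With an estimated correlation the adjusted p of these lists lay between 0.527 and 0.740. With 1 mouse left out the means ranged from -0.0798 to -0.0326 for niacin, -0.0693 to -0.0164 for insulin, -0.115 to -0.020 for lipogenesis, -0.139 to -0.0694 for lipolysis and -0.120 to -0.0389 for adipocyte identity. In the niacin receptor and NAD metabolism list 12 of 18 members lay below 0 (mean -0.0526, camera adjusted p = 0.189), among them the deacetylase Sirt1 (-0.42, SE 0.16) and Nampt, the rate-limiting enzyme of NAD salvage (-0.36, SE 0.16). The niacin receptor gene Hcar2 read 546 ± 280 in placebo and 744 ± 205 in NBC mice (SD, n = 4 each; log2 difference 0.53, SE 0.37). Over the alternatives the Hcar2 difference ranged from 0.210 to 1.19. In the insulin signalling list 15 of 25 members lay below 0 (mean -0.0433, adjusted p = 0.249). Its member Socs3, a suppressor of cytokine and insulin signalling, was 0.77 (SE 0.21) higher without overlap (its other kept probe sets gave 0.55 and 1.23, with overlap), and the adipocyte insulin receptor substrate Irs3 differed by -0.42 (SE 0.14), also without overlap. The lipogenesis list (mean -0.0758, adjusted p = 0.198) held Pck1, which supplies glycerol 3-phosphate in fat, at -0.80 (SE 0.22). The lipolysis and lipid droplet list averaged -0.101 (adjusted p = 0.0697), with the hormone-sensitive lipase Lipe at -0.19 (SE 0.11) and the glycerol channel Aqp7 at -0.48 (SE 0.25), or -0.17 (SE 0.21) in its second kept probe set, 1418848_at. This list also held the recalled gene Cidea (-0.996), and its median was -0.110. The adipocyte identity list averaged -0.0864 (adjusted p = 0.0879), with the regulator Pparg at -0.23 (SE 0.12) and the insulin-responsive glucose transporter Slc2a4 at -0.28 (SE 0.18), or -0.67 (SE 0.27) in its second kept probe set, 1415959_at. Over the alternatives the Slc2a4 difference ranged from -0.630 to -0.130. The antioxidant list averaged 0.0255 (adjusted p = 0.784; -0.0650 to 0.0583 with 1 mouse left out) and held the tocopherol transfer protein Ttpa, another gene recalled from the study, at 1127 ± 107 in placebo and 792 ± 87.2 in NBC mice (SD, n = 4 each; log2 difference -0.50, SE 0.13, no overlap).

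Among the transcripts that check the samples, the leptin gene Lep read 87898 ± 7052 in placebo and 85039 ± 8339 in NBC mice (SD, n = 4 each; log2 difference -0.049, SE 0.12). The leptin receptor gene Lepr differed by 0.099 (SE 0.36), and Xist lay below the filter at 308 ± 88.9 and 216 ± 69.2 (SD, n = 4 each). The Gapdh 3' to 5' ratio averaged 0.968 ± 0.055 in placebo and 1.18 ± 0.26 in NBC mice (SD, n = 4 each; exact two-sided permutation p = 0.229), and the beta-actin ratio 1.64 ± 0.11 and 1.75 ± 0.27 (SD, n = 4 each; exact two-sided permutation p = 0.514). These group means hide single arrays. The beta-actin ratio too was highest in NBC mice 5 (2.10) and 11 (1.82), against 1.51 to 1.74 in all other mice. On the first principal component, the axis along which the arrays differed most, NBC mice 5 and 11 stood at 44.2 and 42.4. All other arrays lay between -28.6 and 1.20 on it.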

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

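The explanation tests and the split counts in this part were all chosen after the results were seen. A mouse was singled out where its gap to the nearest mouse of its group took up an unusually large share of the group's range (Dixon's ratio at the 95% level). This held for 17 of 198 groups of 4 values, where chance alone gives about 9.9, and many of the values tested are correlated.

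NBC mouse 9 lay below the other 3 NBC mice in 11 of the 17 cases. One of them, Apobec2, was named because it passed only without this mouse, so its case follows from how it was chosen and 10 remain. The ratio was 0.915 for the muscle contraction score, 0.959 for the muscle calcium handling and energy score, 0.947 for Eno3, 0.869 for Pvalb, 0.914 for Casq1, 0.955 for Actn3, 0.918 for Tnni2, 0.907 for Tnnc2, 0.907 for Mylpf, 0.876 for Ckm and 0.928 for Apobec2. The remaining cases were Cidea, with NBC mouse 11 below the others (0.835), Ucp1 and the thermogenesis score, with placebo mouse 10 below the others (0.925 and 0.920), Mtcl1, with placebo mouse 14 above (0.869), and Mmp14 and the antioxidant score, with NBC mouse 13 above (0.971 and 0.961).

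Skeletal muscle transcripts stood far above placebo in 3 of 4 NBC mice. A candidate explanation is skeletal muscle tissue in the collected fat in varying amount, which stays open. Over the 4 placebo mice the 36 measured members of both muscle lists had a mean pairwise correlation of 0.458. Of the 25 other lists, 3 had as high a value, and without placebo mouse 10 the muscle value was 0.123. Genes expressed together would vary together as well, so this correlation does not speak for muscle tissue. The alpha-actin gene Acta1, picked as an abundant muscle transcript after its values were seen, read 2408 to 11040 in placebo and 8181 to 30882 in NBC mice. RNA integrity stays open too, since with the Gapdh 3' to 5' ratio in the fit the group difference of the contraction score was 1.36 (95% interval -0.100 to 2.81) against 2.12 without it. An effect of supplementation on muscle transcripts stays open too, because the exact permutation p of the score was 0.0571 and NBC mouse 9 lay at the placebo level. A response limited to 3 of the 4 mice was not tested, and these 8 arrays do not decide between it and muscle tissue collected with the fat.

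Cidea and Ucp1 had lower means in NBC mice. Dilution of adipocyte RNA by other RNA is argued against, since the adipocyte list had a median log2 difference of -0.0882 (SD 0.141 over members) where Cidea differed by -0.996. RNA integrity as the whole cause is argued against for Cidea, whose difference with the Gapdh ratio in the fit was -0.964 (95% interval -1.57 to -0.354). Fewer brown or beige adipocytes in the depot stay open. The other 16 measured thermogenesis members had a median of -0.0898 and ranged from -0.62 to 0.44, and several are also expressed by white adipocytes or muscle, which keeps a small change in cell share hidden. An effect of supplementation on these 2 genes stays a hypothesis, as Cidea passed only adjusted over the list alone and both genes were recalled from the study.

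The counts were set against all 35 splits of the 8 arrays into 4 and 4. As many probe sets at an unadjusted p under 0.05 as in the real split (1400) were found in 10 of the 35 splits, with 2448 as the highest of the others, so chance is not excluded for this count. The split with 2448 set placebo mice 6 and 10 with NBC mice 5 and 11 against the rest. With 0 probe sets past the adjusted threshold in the real split, all 35 splits had to give at least as many, so this count tests nothing. The highest of the others gave 1, in the split that sets placebo mice 6, 8 and 14 with NBC mouse 9 against the rest, which follows the muscle transcripts. As many lists past camera's threshold with the preset correlation as in the real split (7) were found in 12 of the 35 splits, with 12 as the highest of the others, so chance is not excluded for the number of lists either.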

How the results depend on the processing

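Tests with the Gapdh ratio as a covariate or without NBC mice 5 and 11 were chosen after the data were seen. No paired analysis was possible because no mouse number occurs in both groups. Over 22 alternatives, 1296 of 1308 values of the 69 genes examined kept their direction and side of the threshold, 8 gained a call, all without NBC mouse 9, and 4 reversed. None of these genes passed as reported, so keeping the side meant still not passing, and this count does not measure stability. Sizes could move widely, from -0.564 to -0.0294 for Sirt1 and from 0.654 to 5.04 for Actn3. The Actn3 range includes the fit with the muscle contraction score as a covariate. Actn3 is a member of that score, so a smaller difference in that fit does not measure dependence on processing. The 7 lists past the threshold kept direction and call in 122 of 147 values and lost the call in 25, and the 20 others kept theirs in 351 of 418, gained a call in 41 and reversed in 26. Calls were gained by lipolysis (8 alternatives), thermogenesis (7), lymphocytes (6), adipocyte identity (5), the cell cycle (4), smooth muscle, immediate early genes and the circadian clock (3 each), and lipogenesis and erythroid cells (1 each). Signals near the filter and the spread between 4 mice limit what can be called. Except where fewer arrays or probe sets were tested, the cause was not tested.

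Probe sets past the threshold numbered 0 under all alternatives except without NBC mouse 9, so that the range with 1 array left out was 0 to 18 (0 to 14 genes by their representative probe sets, and 17 genes by any probe set without NBC mouse 9). Probe sets at an unadjusted p under 0.05 numbered 2396 with no filter, 884 with the stricter filter, 2126 with array weights, and 1037 to 2549 with 1 array left out, the highest without NBC mouse 9, where 35.7% were higher in NBC against 52.8%. Lists past the threshold numbered 11 with trend and robust settings, 11 with the Gapdh ratio as a covariate, 0 with an estimated correlation, 0 with fry's directional test, and from 5 (without NBC mouse 9) to 14 (without NBC mouse 5) with 1 array left out.

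With an estimated correlation and with fry's directional test the list means stayed as they were and the calls were lost, with adjusted p of 0.218 and 0.137 for muscle contraction (2.12), 0.218 and 0.137 for muscle calcium handling and energy supply (1.58), 0.129 and 0.0651 for fatty acid oxidation (-0.156), 0.218 and 0.0996 for the mitochondrial list (-0.0898), 0.218 and 0.0734 for metal transport (0.167), 0.395 and 0.25 for extracellular matrix (0.153), and 0.534 and 0.546 for macrophages (0.274). Over all alternatives the adjusted p of these lists ranged from 1.6e-25 to 0.218, 2.1e-23 to 0.218, 1.3e-05 to 0.129, 4.6e-05 to 0.218, 0.0060 to 0.218, 1.4e-07 to 0.395 and 1.4e-10 to 0.546, in that order. Metal transport also lost its call with no filter (0.108), with the mean of all probe sets of a gene (0.0859) and without NBC mice 5 and 11 (0.151), the mitochondrial list with the mean of all probe sets (-0.0768) and the macrophage list with array weights (0.128). With 1 array left out, means ranged from 0.142 to 0.182 for metal transport, -0.106 to -0.0736 for the mitochondrial list and 0.0944 to 0.407 for macrophages.

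The list reversals concerned lists that had missed the threshold. With no filter, skin and epithelium gave -0.0208 and nerve -0.0842. With the mean of all probe sets, antioxidants gave -0.0225, nerve -0.0227, cholesterol synthesis -0.00594 and Tpm1 0.61. With array weights the cell cycle gave -0.0710. With the Gapdh ratio as a covariate, glycolysis gave -0.0236 and nerve -0.0139, and without NBC mice 5 and 11, glycolysis -0.0261, endothelium -0.0464, nerve -0.0233 and endoplasmic reticulum stress 0.0299. With the muscle score as a covariate, Pfkm went from 0.49 to -0.0899, Lep from -0.049 to 0.0462 and Cd79a from -1.19 to 0.54. With 1 array left out the ranges were -0.0564 to 0.134 for endothelium, -0.0217 to 0.0750 for cholesterol synthesis, -0.0163 to 0.0625 for glycolysis, -0.0625 to 0.167 for skin, -0.0148 to 0.0433 for nerve, -0.103 to 0.135 for the cell cycle and -0.0650 to 0.0583 for antioxidants.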

Other observations

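Transcripts of lymphocytes split the NBC mice. The lymphocyte and lymph node score was -1.25 and -1.32 in NBC mice 13 and 11, 0.68 and 0.94 in NBC mice 9 and 5, and 0.032 to 0.46 in placebo mice (exact two-sided permutation p = 0.429). Cd79a, a subunit of the B cell receptor, read 251 and 79.0 in NBC mice 13 and 11, 1587 and 1464 in NBC mice 9 and 5, and 925 to 1287 in placebo mice. The list mean was -0.472 (camera adjusted p = 0.0697, and 0.740 with an estimated correlation). It varied with the mouse left out, with -0.864 without NBC mouse 5 (camera adjusted p = 7.8e-06) and -0.112 without NBC mouse 11. The list passed in 6 of 21 alternatives, among them those without placebo mouse 10 (-0.540, adjusted p = 0.0334) and without NBC mouse 9 (-0.778, adjusted p = 0.0041).

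The circadian list missed the threshold, with 9 of 16 members above 0 and a mean of 0.112 (camera adjusted p = 0.143, and 0.534 with an estimated correlation). Its members with the smallest p were Npas2, a partner of the core clock activator (0.71, SE 0.20), Nfil3 (0.45, SE 0.17) and Bhlhe40 (0.50, SE 0.21). Each overlapped between the groups, and no member passed adjusted over the list alone. This list passed without placebo mouse 10 (0.155, adjusted p = 0.0409), without NBC mouse 5 (0.135, adjusted p = 0.0455) and with the Gapdh ratio as a covariate (adjusted p = 0.0301), the last chosen after the data were seen. Fry's directional test gave an adjusted p of 0.525, and its test for change in either direction 0.0441 for this list, the same value as for 6 others, and 0.0463 for insulin signalling. The hour at which each mouse was killed is not given in the sources used here.

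The other lists missed the threshold of camera with the preset correlation. Means and adjusted p were 0.144 and 0.392 for muscle development regulators (4 members measured), 0.0209 and 0.784 for glycolysis, whose member Pfkm, the muscle phosphofructokinase, was 0.49 (SE 0.22) higher, 0.0317 and 0.784 for endothelium, 0.0865 and 0.509 for skin and epithelium, 0.0162 and 0.853 for nerve and Schwann cells, 0.189 and 0.189 for smooth muscle, -0.520 and 0.143 for erythroid cells (3 members measured), 0.120 and 0.0850 for immediate early and heat shock genes, -0.0295 and 0.784 for endoplasmic reticulum stress, 0.0172 and 0.784 for cholesterol synthesis and 0.0446 and 0.399 for the cell cycle. Leaving out a single mouse gave a call to smooth muscle (without placebo mouse 10, 0.310, adjusted p = 0.0045, or NBC mouse 13, 0.268, 0.0457), whose median was only 0.0472 over all mice and which holds Des (1.3, SE 0.44), and to erythroid cells (without NBC mouse 11, -0.751, 0.0220). It also gave one to immediate early genes (without placebo mouse 6, 0.199, 0.0021, placebo mouse 8, 0.151, 0.0470, or NBC mouse 5, 0.175, 0.0169) and to the cell cycle (without placebo mouse 14, 0.122, 0.0332, or NBC mouse 5, 0.135, 0.0455). The cell cycle list also passed camera with the Gapdh ratio as a covariate (0.194, adjusted p = 0.0082). It passed too without NBC mice 5 and 11 (0.272, camera adjusted p = 0.00081), and both settings were chosen after the data were seen. With an estimated correlation the adjusted p was 0.688 for smooth muscle, 0.534 for erythroid cells, 0.562 for immediate early genes and 0.889 for the cell cycle. With 1 mouse left out the means ranged from 0.101 to 0.310 for smooth muscle, -0.751 to -0.293 for erythroid cells, 0.0620 to 0.199 for immediate early genes and -0.103 to 0.135 for the cell cycle. The ranges were 0.0767 to 0.194 for muscle development regulators and -0.0702 to -0.00128 for endoplasmic reticulum stress.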
